A study of Ulmus pumila with 3 samples.

How the data were processed

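Small RNA of 3 root samples of Ulmus pumila seedlings, 30 days old, was sequenced, 1 library per condition (control, 50 mM NaCl for 6 h and 200 mM NaCl for 24 h). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an NEBNext small RNA kit for Illumina sequencing. Groups were taken from the description of each sample. Adapter trimming, aligner, mismatches allowed, reference and strand handling are not given in the sources used here. Each table lists miRNA family, name, sequence and 2 measurements per name.

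The read counts were deposited by the authors as whole numbers per miRNA name, per the file headers. The TPM values deposited by the authors are, as checked on every name, the count per 1000000 of the sum of counts in the same table, worth 1.96 TPM per read in the control library, 2.22 at 50 mM and 1.83 at 200 mM. They carry no correction for length and are called RPM in the text. Only names with at least 1 read are listed per library, so a name absent from a table was taken as 0 counts, and it entered no list median. In the count of differing names with no count minimum, its ratio was computed against 3 counts. The largest count of a name not listed in all 3 libraries was 13. The totals, 509280, 449522 and 545587 counts, are sums over names and not the sequencing depth, which is not given in the sources used here.

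Names of overlapping sequence often carry the same or nearly the same counts, and so do some names of complementary sequence, so reads were counted under more than 1 name. Joining names that overlap by at least 16 nt on either strand with at most 2 mismatches, and whose counts lie within 5% or 3 reads in all 3 libraries, left 201 names of the 309 and 59.8%, 62.3% and 66.5% of the totals. Intervals over lists are for this reason too narrow. Those of families take the width of the most counted name instead, though a family's ratio still counts shared reads more than once. The name miR171g is given to 2 sequences, kept apart here, and 1 sequence has 2 names. No name carries the prefix of a species other than elm. No reference genome was used here, so no coordinates are given, and the leading names are identified by sequence.

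With 1 library per group, no test between conditions and no p-value was computed. For each pair of libraries the ratio of RPM was computed with an exact 95% interval (conditional binomial, Clopper-Pearson), which compares these libraries and covers counting error only; amplified reads are not independent molecules. A name was compared when it was in both libraries with at least 20 counts in 1 of them, and called higher or lower when its ratio was at least 2 in either direction and the interval excluded 1. Levels have exact Poisson intervals and shares exact binomial ones. Family values are summed over names with the number of the family, and the interval of a family is as wide as that of its most counted name.

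The lists of families were fixed before the data were examined: auxin-linked (miR160, miR164, miR167, miR390, miR393), phase-change (miR156, miR157, miR172, miR535), growth transcription-factor (miR159, miR165, miR166, miR169, miR170, miR171, miR319, miR394, miR396), nutrient (miR395, miR399, miR778, miR827, miR2111), copper (miR397, miR398, miR408, miR857), small RNA pathway (miR162, miR168, miR403) and disease-resistance gene families (miR472, miR482, miR1507, miR2109, miR2118, miR5300). No listed name carries the number of miR390, miR778, miR857, miR168, miR472, miR2109, miR2118 or miR5300, so these families entered no list median. The names of miR169, miR170, miR172, miR395, miR1507 and miR2111 each stayed under 20 counts in every library. A list is described by the median log2 ratio of its compared names minus the median of all compared names, with an interval from 2000 Poisson resamples. Its percentile is among 10000 random lists of the same size, drawn from the 15 neighbours by abundance on each side of each member. The comparisons with control share 1 library, so shared names were set beside 1000 simulations of unchanged libraries and beside the number for independent lists. Only the salt libraries were drawn in these simulations, with the control counts kept fixed.

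The named miRNAs follow a rule fixed at the same time. It takes the 10 most abundant names of the control library, up to 10 higher and 10 lower names per comparison ranked by the interval bound nearest to 1, every listed family and the 5 most abundant new names over all libraries. Other names in the text were chosen after their values were seen, among them miR164a, miR399a, miR399b and those of the closing section. The rule of size was tested on simulated Poisson counts of 309 names in 50 simulations, each with 40 changed names. It recovered 92.8%, 93.4% and 94.1% of 2.5-fold differences at 50 mM against control, 200 mM against control and between the salt libraries, and 98.7%, 98.9% and 99.9% of 4-fold differences. It called 0.524%, 0.465% and 0.550% of unchanged names. These rates cover Poisson counting error only. The simulations held no difference between seedlings or library preparations and no reads shared between names, so they are not error rates between conditions.

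Alternatives were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without the most abundant name, a count minimum of 50 or none, a ratio of at least 1.5 or 4, identical sequences counted once and 1 value per family. Joining of near-equal names, with totals recomputed or left unchanged, was added after the data were seen. edgeR and DESeq2 gave scaling factors only. The TMM factors were 1.10, 1.05 and 0.868 and the size factors 1.12, 0.951 and 0.935, in the order control, 50 mM and 200 mM. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.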

Results

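MicroRNAs (miRNAs), the short RNAs that guide silencing of matching transcripts, were counted in the roots of 30-day-old seedlings of Siberian elm (Ulmus pumila). The study asked how the miRNA population of the root differs between unstressed and salt-stressed plants. Its 3 small RNA libraries came from seedlings without added salt (control), from seedlings given 50 mM NaCl for 6 h and from seedlings given 200 mM NaCl for 24 h. Each condition has 1 library, so there are no replicates, and no difference below was tested between conditions. The 95% intervals cover counting error within a library only. The salt dose and the time differ together between the salt libraries and cannot be separated.

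The counts of all named miRNAs summed to 509280 in the control library, 449522 in the 50 mM library and 545587 in the 200 mM library. The libraries held 293, 283 and 281 names in that order, and 244 of the 309 names were in all 3. Of these 309, 245 carry a conserved family number, from 46 families, and 64 are miRNAs that the authors named as new. The new names are written here as new-11-3p, with the running number of the hairpin and its arm. A read could be counted under several names of overlapping sequence, so sums over names count some reads more than once.

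Members of miR159, a family that targets GAMYB-like MYB factors, and of miR166, which targets HD-ZIP III factors, filled most of each library. miR159a (UUUGGAUUGAAGGGAGCUCCU) stood at 158467 RPM (reads per 1000000 counts of all names) in the control library (95% interval 157375 to 159564), 180783 at 50 mM (179542 to 182030) and 240064 at 200 mM (238766 to 241368). The other 9 of the 10 most abundant names of the control library were miR159b, at 93279 RPM, miR159c, miR159d, miR166a to miR166d, new-1-5p and new-15-3p. The names miR166a (UCUCGGACCAGGCUUCAUUC) to miR166d had near-equal counts, between 35087 and 36464 in the control library. Summed over its names, miR166 stood at 305209 RPM in the control library, 269473 at 50 mM and 225106 at 200 mM. New miRNAs took 15.05% of the counts in the control library (exact binomial interval 14.9% to 15.1%), 17.0% at 50 mM (16.9% to 17.1%) and 13.2% at 200 mM (13.1% to 13.3%). The most abundant new name, new-1-5p (ACUCUCCCAUUAAGGCUUCUG), had 25228, 27533 and 23086 counts. new-15-3p (GAAGCCUUAAUGGGAGAGUGA), complementary to it over most of its length, had 25137, 27442 and 22975. The other most abundant new names were new-36, new-4-3p and new-1-3p, at 16832, 5229 and 2075 RPM in the control library.

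In the library from 50 mM NaCl for 6 h, the families linked to phosphate supply stood higher than in the control library, and the main copper-responsive families stood lower. miR399, which targets the PHO2 ubiquitin conjugase of phosphate homeostasis, was at 999 RPM against 544, a ratio of 1.84 (1.5 to 2.25). Its most counted name, miR399a, had a smaller ratio, 1.37 (1.12 to 1.68). miR827, which targets SPX-domain genes of phosphate transport, was at 1713 against 966, a ratio of 1.77 (1.56 to 2.02). miR398, which targets copper/zinc superoxide dismutases, stood at 0.693 of its control level (0.592 to 0.809), and miR408, which targets plantacyanin and laccase genes, at 0.708 (0.622 to 0.806). Few single names differed by a wide margin: of 162 compared, 3 were higher and 5 lower by the fixed rule of size (a ratio of at least 2, at least 20 counts in a library, and an interval that excludes 1).

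The largest ratio in that comparison belonged to miR399c (UGCCAAAGGAGAUUUGCCCCG), with 96 counts against 14, which is 7.77-fold higher (4.41 to 14.7). new-21-5p (UCAUAGAUUAAUAGUGCCAAU) was 2.19-fold higher (1.57 to 3.07) and new-3-5p (AGGGCAUCUCUUCAUUGGCAAG) 2.15-fold higher (1.998 to 2.31). Among the lower names, miR5072 (CGAUUCCCCAGCGGAGUCGCCA) was 4.51-fold lower (2.18 to 10.5) and miR3711 (UGGCGCUAGAAGGAGGGCCU) 3.90-fold lower (2.06 to 8.02). miR8175 (GAUCCCCGGCAACGGCGCCA), with 112 counts against 317, was 2.498-fold lower (2.01 to 3.13). miR166p was 2.77-fold lower (1.14 to 7.69) and miR156e 2.47-fold lower (1.17 to 5.70), both on 10 or fewer counts in the salt library. miR5072, miR3711 and miR8175 were not compared with tRNA or rRNA sequences here.

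**Figure D1:**
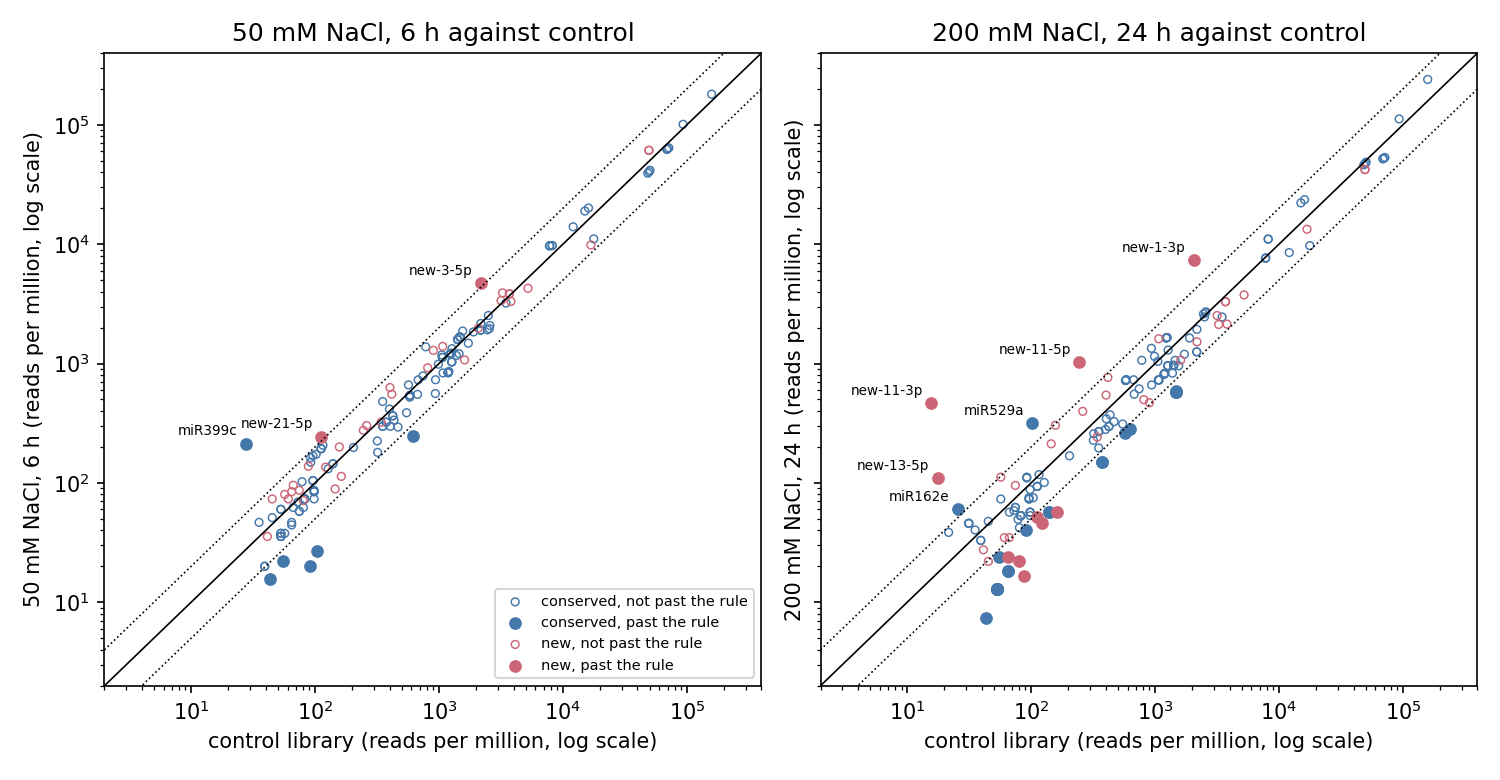
RPM (reads per 1000000 counts) of each compared miRNA name in the control library (x axis, log scale) against the library from 50 mM NaCl for 6 h (left) or 200 mM NaCl for 24 h (right, y axes, log scale), with equality as a solid line and 2-fold ratios as dotted lines. Filled points passed the rule of size, 3 higher and 5 lower on the left and 6 higher and 28 lower on the right, and the higher ones carry their names.

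By family list, each median log2 ratio is given relative to the median of all compared names, and set among 10000 random lists matched on abundance as a description of these libraries. The nutrient list (6 names of miR399 and miR827, 1 higher, 0 lower) had a relative median of 0.89 (0.63 to 1.08), at percentile 99.9. The copper list (12 names, none past the rule) had −0.42 (−0.53 to −0.29), at percentile 0.12, and at 1.81 with overlapping names of near-equal counts joined into 7. miR397, its laccase-targeting family, had a ratio of 1.15 with an interval that includes 1 (0.757 to 1.76). The auxin-linked list (27 names, none past the rule) had −0.11, with an interval that includes 0 (−0.23 to 0.01), and 0.031 with 1 value per family. Within it miR393, which targets the TIR1/AFB auxin receptors, had a ratio of 1.72 (1.23 to 2.43). miR160 and miR167, which target auxin response factors, had 1.13 (1.02 to 1.25) and 0.831 (0.774 to 0.891), and miR164, which targets NAC factors, 0.794 (0.509 to 1.25), with its most counted name, miR164a, at 1.303 (0.834 to 2.04). The small RNA pathway list (5 names, none past the rule) had 0.26 (0.11 to 0.36), and 0.18 over 9 names with no count minimum, with miR162, which targets DCL1, at a ratio of 1.18 (1.13 to 1.23) and miR403, which targets AGO2, at 1.13 (0.997 to 1.27). miR482, which targets NBS-LRR resistance genes, had 1.16 (1.12 to 1.20).

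The growth transcription-factor list (61 names, 0 higher, 1 lower) lay close to all names, with −0.07 (−0.13 to −0.02), and turned to 0.088 with 1 value per family. In it, miR159 had a ratio of 1.01 (0.996 to 1.02), miR166 of 0.883 (0.869 to 0.897) and miR319, which targets TCP factors, of 1.20 (1.17 to 1.24). With near-equal names joined, miR159 had 1.07 (1.06 to 1.08) and miR166 0.840 (0.829 to 0.852). The most counted name of miR159, miR159a, had 1.14 (1.13 to 1.15). The phase-change list (7 names, 0 higher, 1 lower) had −0.14, with an interval that includes 0 (−0.22 to 0.09), and 0.031 with 1 value per family, with miR156, which targets SPL factors, at a ratio of 0.921 (0.832 to 1.02).

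In the library from 200 mM NaCl for 24 h, both arms of new hairpin 11 stood far above the control library, and the miR160 and miR171 families stood below it. new-11-3p (UCAUAUUUGUUUCACUGCCUGUUG) had 253 counts against 8, which is 29.5-fold higher (14.8 to 69.1), and new-11-5p (ACAGGCGGUGGAUCAAAUAUGAAU) had 562 against 125, which is 4.20-fold higher (3.45 to 5.14). miR160 was at 2650 RPM against 6560, a ratio of 0.404 (0.353 to 0.461). miR171, which targets GRAS factors, was at 4375 against 7183, a ratio of 0.609 (0.544 to 0.681).

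Of 168 names compared, 6 were higher and 28 lower. With overlapping names of near-equal counts joined, 6 were higher and 23 lower, or 6 and 17 with the totals left unchanged. Scaling weighed on this split: 10 were higher and 20 lower with TMM factors, 10 and 15 with median-of-ratios factors, and 9 and 25 with totals that left out miR159a. The median log2 ratio of all compared names was −0.40, and these scalings moved it up by 0.34, 0.36 and 0.15. In the comparison of the salt libraries the median was −0.23 and moved up by 0.28, 0.30 and 0.11, and at 50 mM against control it was −0.08 and moved up by 0.06, 0.06 and 0.04.

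The other higher names at 200 mM were new-1-3p (GAAGCCUUAAAGGGAGAGUGG), 3.52-fold higher (3.29 to 3.77) with 3986 counts against 1057, new-13-5p (UCAUGGAUAUAUUUCUCGAAAU), 6.22-fold higher (3.07 to 14.3), miR529a (AGAAGAGAGAGAGUACAGCUU), 3.11-fold higher (2.27 to 4.32), and miR162e, 2.37-fold higher (1.21 to 4.91). miR529 is known, like miR156, to target SPL factors. Of the 28 lower names, 5 were miR160a to miR160e, 7 were miR164b to miR164h and 6 were names of miR171. Of these, 3, 7 and 4 stayed past the rule with TMM factors, and 0, 7 and 2 with median-of-ratios factors, where miR160a to miR160c had a log2 ratio of −0.99. miR160d (UGCCUGGCUCCCUGUAUGCCA) was 2.51-fold lower (2.20 to 2.87). The names miR160a, miR160b and miR160c had identical counts in every library, 755, 747 and 316, and were 2.56-fold lower (2.24 to 2.93). miR171e (UUGAGCCGCGUCAAUAUCUCU) and miR171f also shared their counts and were 2.53-fold lower (1.94 to 3.32). Of new names, new-18 (GUGCAAUUCUCCUUUGGCAGC) was 5.36-fold lower (2.59 to 12.5), new-24 3.66-fold lower (1.89 to 7.65) and new-38-5p 2.87-fold lower (1.88 to 4.48). The name new-38-5p shares 20 nt exactly with miR160b on the same strand, though their counts were not near-equal. Its lower level is therefore not shown to be separate from that of the miR160 names. miR166p, with 4 counts against 22, was 5.89-fold lower (2.001 to 23.5).

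**Figure D2:**
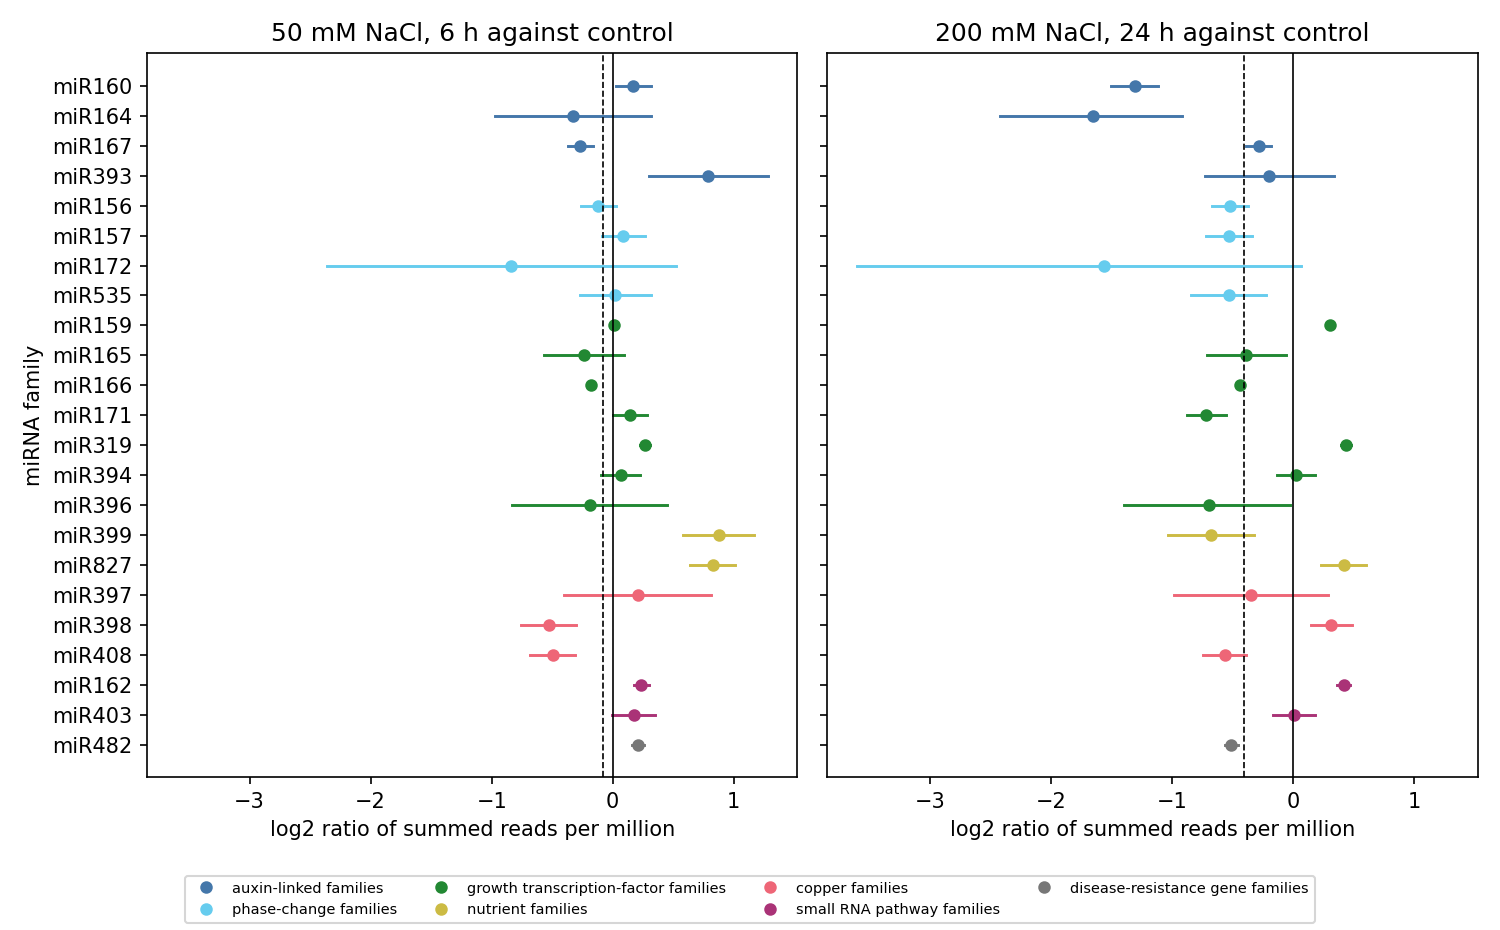
Log2 ratio of summed RPM of each listed miRNA family (points) with 95% counting intervals (bars), for 50 mM NaCl for 6 h (left) and 200 mM NaCl for 24 h (right) against control, coloured by family list. Solid lines mark 0 and dashed lines the median of all compared names, −0.08 on the left and −0.40 on the right. On the right, miR164, miR172 (each name under 20 counts) and miR160 lie farthest below the dashed line. On the left, miR399 and miR827 lie farthest above it.

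The auxin-linked list (27 names, 0 higher, 12 lower) had a relative median of −0.39 (−0.52 to −0.245), at percentile 0.40, but −0.16 and percentile 25.8 once near-equal names were joined into 15. Its 12 lower names all belong to miR160 and miR164, and were 10 with TMM factors and 7, all of miR164, with median-of-ratios factors. The summed miR164 had a ratio of 0.318 (0.187 to 0.531), carried by miR164b to miR164h, which form 2 groups of near-equal counts (miR164b with miR164c, and miR164d to miR164h). Its most counted name, miR164a, had 27 counts against 40, a ratio of 0.630 (0.372 to 1.05), and with near-equal names joined the family had 0.411 (0.281 to 0.591). miR167 had a ratio of 0.824 (0.767 to 0.885), and its direction turned with TMM and median-of-ratios factors, to log2 ratios of 0.057 and 0.084. miR393 had a ratio of 0.874, with an interval that includes 1 (0.604 to 1.27), and log2 ratios of the other sign, 0.14 and 0.17, with those factors. The small RNA pathway list (7 names, 1 higher, 0 lower) had 0.83 (0.59 to 0.89), at percentile 99.1, but at 97.2 with near-equal names joined into 6, and a relative median of 0.56 over 9 names with no count minimum. It had 2 higher names with TMM or median-of-ratios factors. Within it, miR162 had a ratio of 1.34 (1.28 to 1.39) and miR403 of 1.00 (0.892 to 1.13). The nutrient list (5 names, none past the rule) had 0.66 (0.115 to 0.87), and 0.24 over 22 names with no count minimum, while its families parted, with miR827 at a ratio of 1.34 (1.18 to 1.52) and miR399 at 0.627 (0.489 to 0.801).

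The copper list at 200 mM (12 names, none past the rule) had a relative median of 0.01 (−0.16 to 0.19), and −0.055 with no count minimum, with miR398 at a ratio of 1.25 (1.11 to 1.4) and miR408 at 0.676 (0.598 to 0.765). The growth transcription-factor list (61 names, 0 higher, 7 lower) had 0.00 (−0.03 to 0.06), and 5 or 3 lower names with TMM or median-of-ratios factors. In it, miR159 had a ratio of 1.24 (1.23 to 1.25), miR319 of 1.35 (1.32 to 1.39) and miR166 of 0.738 (0.726 to 0.749), a log2 ratio of −0.44. The phase-change list (7 names, 0 higher, 1 lower) had −0.12 (−0.26 to −0.03), and no lower name with TMM or median-of-ratios factors. In it, miR156 had a ratio of 0.697 (0.629 to 0.772). miR482 had 0.703 (0.676 to 0.730), a log2 ratio of −0.51.

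**Figure D3:**
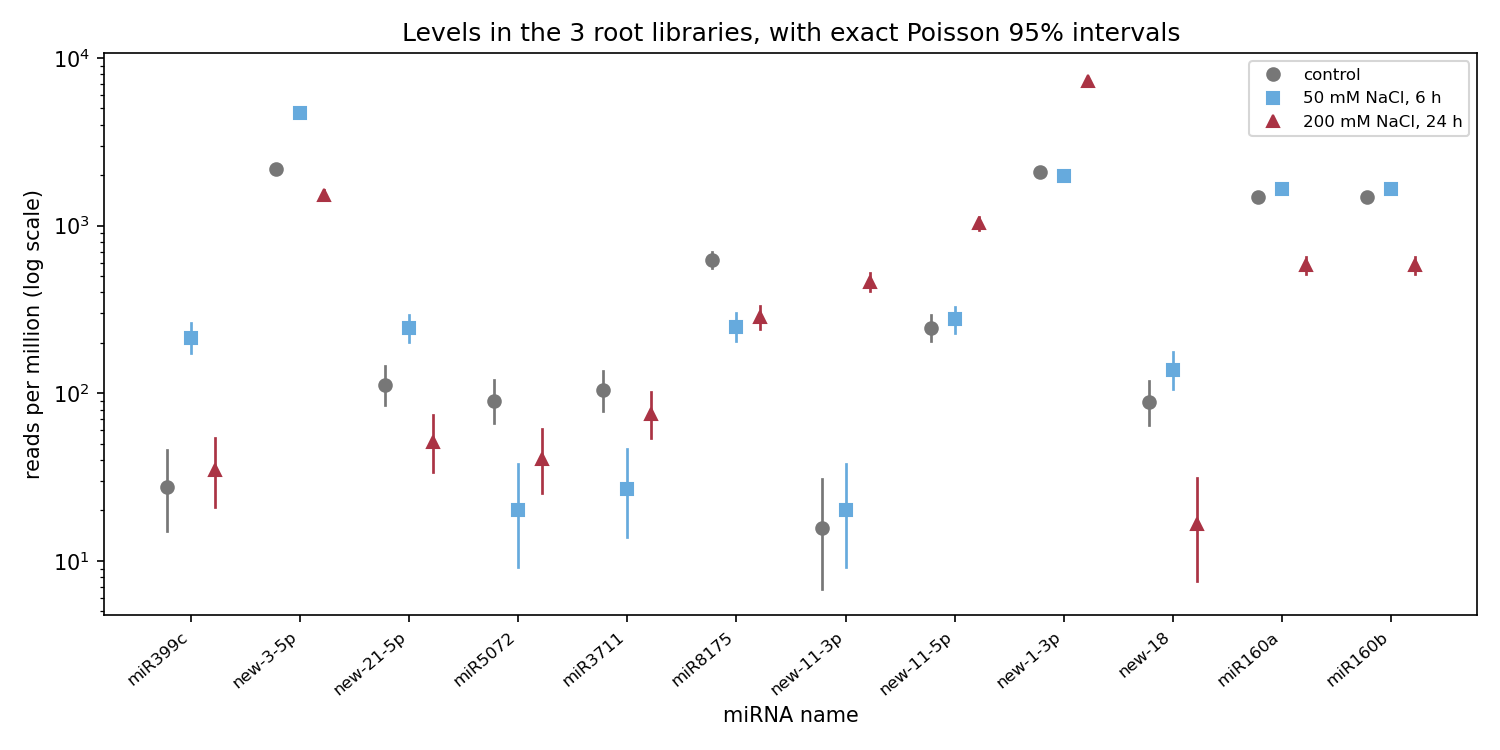
RPM (reads per 1000000 counts) (y axis, log scale) of the 3 leading names by interval in each direction of each comparison with control, in the 3 libraries (grey circles control, blue squares 50 mM NaCl for 6 h, red triangles 200 mM NaCl for 24 h), with exact Poisson 95% intervals as bars. new-11-3p has 8, 9 and 253 counts in that order, and miR399c has 14, 96 and 19.

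Between the salt libraries, the longer and stronger treatment had lower miR160, miR399 and miR171 levels and a higher miR398 level. miR160 stood at 0.359 of its level at 50 mM (0.314 to 0.409), miR399 at 0.341 (0.268 to 0.432) and miR171 at 0.551 (0.493 to 0.615), while miR398 had a ratio of 1.80 (1.56 to 2.09). In this comparison 10 names were higher and 30 lower; the split was 13 and 20 with TMM factors, 13 and 19 with median-of-ratios factors, 11 and 25 without miR159a in the totals, 8 and 23 with near-equal names joined, and 8 and 21 when the totals were left unchanged by joining. new-11-3p was 23.2-fold higher (12.01 to 51.2), new-13-5p 4.94-fold (2.51 to 10.8), new-11-5p 3.73-fold (3.07 to 4.57), new-1-3p 3.69-fold (3.43 to 3.98) and miR398a (UGUGUUCUCAGGUCGCCCCUG) 2.39-fold (2.07 to 2.77). new-15-5p was also 2.39-fold higher (1.65 to 3.51) and miR3711 2.82-fold (1.45 to 5.88). The overlapping names miR1511, miR5139 and miR8155 had the same counts, 25 against 7, and were 2.94-fold higher (1.24 to 8.06).

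The lower names of that comparison were led by new-18, 8.36-fold lower (4.13 to 19.1), miR399c, 6.13-fold lower (3.72 to 10.6), and new-21-5p, 4.77-fold lower (3.13 to 7.50). new-3-5p was 3.08-fold lower (2.84 to 3.34) and new-7-3p 2.75-fold lower (2.37 to 3.20). The names miR160a to miR160d were each 2.87-fold lower, and miR160e 2.53-fold lower (2.07 to 3.11). The auxin-linked list (22 names, 0 higher, 11 lower) had a relative median of −0.70 (−0.77 to −0.33), at percentile 0.06, and −0.28 at percentile 7.20 with near-equal names joined into 14; its 11 lower names were 5, all of miR160, with TMM or median-of-ratios factors. The nutrient list (6 names, 0 higher, 3 lower) had −0.63 (−0.93 to −0.35), and −1.25 over 16 names with no count minimum; its 3 lower names were miR399a, miR399b and miR399c, and only miR399c stayed past the rule with median-of-ratios factors. The small RNA pathway list (7 names) had 0.41 (0.28 to 0.51), the copper list (10 names, 1 higher) 0.19 (0.07 to 0.31), the growth transcription-factor list (60 names, 6 lower, or 4 with TMM or median-of-ratios factors) 0.01 (−0.0032 to 0.10), the phase-change list (6 names) −0.20 (−0.36 to −0.07) and miR482 −0.48 (−0.54 to −0.405). miR166 had a ratio of 0.835 (0.822 to 0.849), but its direction turned with TMM and median-of-ratios factors, to log2 ratios of 0.019 and 0.044.

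Both salt libraries had lower levels than the control library of 4 names, miR156e, miR166p, miR5072 and miR8175, and shared no higher name. miR8175 stood at 0.400 of the control level (0.320 to 0.498) at 50 mM and 0.456 (0.374 to 0.555) at 200 mM, and miR5072 at 0.222 (0.0954 to 0.458) and 0.446 (0.256 to 0.757); neither was compared with tRNA or rRNA sequences here. Unchanged libraries simulated against the same control shared 0.001 lower names on average over 1000 simulations, and independent lists of 5 and 28 among 161 names would share 0.870. These simulations kept the control counts fixed, so they leave out counting error in the shared control. The number for independent lists leaves it out too. The single control library cannot be split, so how much of the excess comes from it is not known. With TMM or median-of-ratios factors, 1 name was shared, miR166p, on 7 counts at 50 mM and 4 at 200 mM against 22. With these factors miR156e, miR5072 and miR8175 were not past the rule at 200 mM. There miR8175 had ratios of 0.576 (TMM) and 0.587 (median of ratios), and miR5072 0.564 and 0.574.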

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

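The tests in this part were all chosen only after the results were seen. new-21-5p went opposite ways in the salt libraries, with a ratio to control of 2.19 at 50 mM for 6 h and 0.459 at 200 mM for 24 h, on 110 and 28 counts against 57. The ratio at 200 mM was 0.579 with TMM factors, 0.590 with median-of-ratios factors and 0.508 with totals that left out miR159a, each under a 2-fold difference, so only the higher level at 50 mM stayed past the rule of size with every scaling. Each side is 1 library, so the difference between the salt conditions was not tested, and dose and time are not separated.

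Both arms of new hairpin 11, 24 nt each, stood higher at 200 mM than in the control library. A larger share of 24-nt RNAs in that library would raise the other 24-nt names too. The 4 others with enough counts had a median log2 ratio of −0.65 and ranged from −1.41 to 0.88 (new-37), below both arms. The arms were picked for their large ratios, so that the others lie below them is no check. The median shows only that these 4 names did not rise together. A rise of some 24-nt names stays open. With TMM or median-of-ratios factors the lower arm had a log2 ratio of 2.41 or more. These factors move every name at 200 mM up by the same amount, 0.34 and 0.36. They could therefore not have lowered the arms, and are no check of the scaling. A response to salt, its dose or its duration stays open and untested, as does any difference between seedlings or library preparations, since the condition has 1 library.

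Lower names outnumbered higher ones at 200 mM. The miR159 names held 40.8% of all counts in the control library and 50.4% at 200 mM. RPM are shares of a total, so a larger miR159 share goes with a smaller share of the other names together. With the 22 miR159 names left out of the totals, the median log2 ratio of the compared names went from −0.40 to −0.15 (−0.19 to −0.10). It was −0.07 with TMM factors and −0.04 with median-of-ratios factors. Both kinds of factor are built to bring the typical ratio of names near equality, so these values are no check of the shift. The size of the shift thus depends on the scaling chosen. Shares cannot tell a gain of miR159 from a fall of the other names, so what lies behind it is not settled. After joining of near-equal names, 23 of 29 names past the rule were lower (79.3%, exact binomial interval 60.3% to 92.0%), or 17 of 23 with the totals unchanged (73.9%, 51.6% to 89.8%), so how far reads counted under several names add to the excess stays open. Also open, and untested with 1 library per condition, is a response to salt or a difference between libraries.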

How the results depend on the processing

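No paired analysis was possible because each condition has 1 library, and for the same reason no replicate could be left out. The alternatives with other pseudocounts were not run because the tables hold counts and no pseudocount was used. A value for a list, family, name or share stayed when it lay inside the interval of its main value. A number of names stayed when within 1.5 times, whichever names made it up. At 200 mM against control it stayed with TMM and median-of-ratios factors. Yet of the 6 higher and 28 lower names, 6 and 20 were kept with TMM factors, and 6 and 15 with median-of-ratios factors. A list or family turned only when its main interval excluded 0 and the alternative had the other sign. Of the alternative values for the 28 main results, 140 stayed close, 28 moved and 1 turned its direction. Of values for families 188 stayed, 88 moved and 4 turned, and of values for single names 143 stayed, 33 moved and none turned. All these single names were past a 2-fold ratio, and their alternatives only changed the scaling, by too little to turn any. That none turned is therefore no check of them. A further 3 values for lists and 18 for families, over 8 pairs of a family and a comparison, took the other sign where the main interval included 0, and are not counted as turned. Both ways of joining near-equal names were chosen after seeing the data. Causes were not tested except where the construction shows them: a higher count minimum or ratio leaves fewer names to pass and a lower one more, and with no count minimum the lists take in names of few reads.

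The number of differing names at 50 mM against control, 8, was 5 with a count minimum of 50, 14 with none, 26 with a ratio of 1.5 and 2 with a ratio of 4. At 200 mM against control, 34 became 18 with a minimum of 50, 23 with near-equal names joined and the totals unchanged, 58 with a ratio of 1.5 and 12 with a ratio of 4. Between the salt libraries, 40 became 26 with a minimum of 50 and 7 with a ratio of 4. The 4 shared names became 1 with TMM factors, 1 with median-of-ratios factors and 7 with a ratio of 1.5. The share of new miRNAs without the most abundant name was 17.9% in the control library, 20.7% at 50 mM and 17.4% at 200 mM, and 16.3%, 16.9% and 13.0% with near-equal names joined.

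With no count minimum, the relative medians of the lists at 200 mM against control were −0.056 for growth transcription-factor, 0.56 for small RNA pathway and −0.17 for disease-resistance families. Between the salt libraries they were −1.25 for nutrient and −0.22 for disease-resistance families. With 1 value per family, the auxin-linked median at 50 mM was 0.031 and the growth transcription-factor median turned to 0.088. Between the salt libraries the same setting gave −0.92 for auxin-linked and 0.24 for small RNA pathway families. With near-equal names joined, the auxin-linked median was −0.16 at 200 mM against control and −0.28 between the salt libraries. This setting joins only overlapping names of near-equal counts, so reads shared by other names may still count more than once. The families that turned were miR167 at 200 mM against control, with log2 ratios of 0.057 (TMM) and 0.084 (median of ratios), and miR166 between the salt libraries, with 0.019 and 0.044. Depth limits the names of few reads: 169 of the 309 reached 20 counts in a library.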

Other observations

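The hairpins of new miRNAs differed in the share of reads from each arm. The 3p arm of hairpin 11 gave 6.02% of its reads in the control library (exact binomial interval 2.63% to 11.5%), 6.77% at 50 mM (3.14% to 12.5%) and 31.0% at 200 mM (27.9% to 34.3%). No share is given for hairpin 1, since the counts of its 5p arm nearly equal those of the complementary new-15-3p and its reads cannot be assigned. In hairpin 9 the 3p share was lower at 200 mM, at 2.76% (1.80% to 4.05%) against 10.2% (7.91% to 12.9%) in the control library. In hairpin 3 it was 45.5% at 50 mM (43.9% to 47.0%) against 59.9% (58.1% to 61.8%) in the control library and 58.3% (56.1% to 60.5%) at 200 mM. These shares do not depend on the scaling of the libraries, and they have no replicate check.

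new-18 (GUGCAAUUCUCCUUUGGCAGC) is exactly complementary over 19 nt to miR399f, and had 45 counts in the control library, 62 at 50 mM and 9 at 200 mM. Like the summed miR399 family, it was highest at 50 mM and lowest at 200 mM. miR858, a family that targets MYB factors and lies outside the fixed lists, was at 15777 RPM in the control library, 19530 at 50 mM and 15433 at 200 mM. The 24-nt new-37 (AUUCAAAUCGUUAUGGUUAAGACU) had a ratio of 1.33 (1.10 to 1.61) at 50 mM and 1.84 (1.56 to 2.18) at 200 mM against control. new-36 (GGGGAUGUAGCUCAGAUGGU), at 16832 RPM in the control library, had ratios of 0.586 (0.565 to 0.607) and 0.793 (0.768 to 0.818), and it was not compared with tRNA or rRNA sequences here. The sequence UGAAGCUGCCAGCAUGAUCU stands under 2 names, miR167c with 1298 counts and new-39-5p with 9 in the control library.

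Equal counts under different names were the widest pattern, and its tests were chosen after it was seen. Of 100 pairs of names that share at least 18 nt exactly on the same strand, both with at least 20 counts in a library, 40% had near-equal counts in all 3 libraries, against 1 of 13631 pairs with no overlap, which is consistent with 1 read being counted under several names. Separate molecules at the same level are argued against: 21 of these pairs had the same count in all 3 libraries, where independent counts would give 0.00327. Among 31 pairs complementary over at least 16 nt, with the same count minimum, 6 had the same counts where independent counts would give 0.000743, so separate molecules at the same level are argued against there too. Not every read was counted on both strands, since 29.4% of 34 such pairs with at least 1 name at the minimum had near-equal counts. How the authors assigned such reads stays open, and no biological explanation was tested.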
